A study of Arabidopsis thaliana with 8 samples.

How the data were processed

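DNA from H3K4me2 chromatin immunoprecipitations and the matching inputs of C24 seedlings had been amplified and labelled directly with Cy3 and Cy5, per the labels' protocols, and hybridised to 8 two-channel arrays. The antibody was directed against H3K4me2. The arrays form 4 dye swaps, one for each of the replicates I to IV, and the labels give the channel that held the IP. All 8 arrays were assigned to 1 group, IP against input in C24.

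The only values used were those of the deposited value table, which holds processed log ratios. Scanner intensities were not used here, so background and dye could not be examined, and signal depth over background is unknown. The software, background correction and normalization behind the log ratios are not given in the sources used here. The authors' table has exactly the same number for both arrays of a dye swap at every feature with a value, and is blank for both elsewhere. The values had therefore been combined over the swap, or copied to both arrays, before deposit. The base of the logarithm is not stated. If the scanner had 16 bits, which is assumed here, raw intensities could not give the range of the values in base 10. Processed ratios need not keep to that limit, so base 10 is unlikely but not excluded. Base 2 and the natural logarithm cannot be told apart. The direction of the ratio is not stated either, and with the same value in both orientations it cannot be read from the dyes. The columns were not centred, with deposited medians of -0.79 (I), -0.46 (II), -0.89 (III) and -0.35 (IV). All results are therefore in deposited log ratio units, and signs are relative to the array median.

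Each replicate's value was the common value of its 2 arrays, minus the median over all tiles with a value. No loess or quantile step was applied, since most tiles of such an array can carry signal. Features whose ID is not of the form of a plate and well (39 controls) and 465 tiles carried no value and were left out. Each tile's mean was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 values per tile, 3 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05. The mixture was fitted with scikit-learn 1.9.0, and other statistics were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The number of arrays limits the precision: a tile's mean had a median standard error of 0.11.

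The design, the alternatives and the rule for named tiles were fixed before the data were examined. The rule named genes where the tiles could be tied to them, and otherwise the 2 highest and the 2 lowest tiles past the threshold with 1 sign in all 4 replicates. No gene names or positions of tiles were used here, so the planned comparisons of genes, gene lists (photosynthesis, cytosolic ribosomal proteins, housekeeping, developmental transcription factors, seed storage, NLR disease resistance and cysteine-rich receptor-like kinases), annotation classes, chromosome regions and positions within genes were not made. The dye effect could not be fitted, because both orientations hold the same values. The comparisons of plates, tile series, neighbouring tiles and runs were added after the data had been seen. They take the plate (the first 4 characters of the ID) and the well from the tile's ID and use its numbering as an order. Plates were called low when the mean over replicates of their centred median was under -1.

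The limma test was tested on simulated data for 21296 tiles with the moderated spread of each tile, with 100 tiles shifted by 0.5 and 100 by 1, up or down. With independent replicates 32% of the shifts of 0.5 and 98% of the shifts of 1 were recovered, 9 unchanged tiles were called, and 5.0% of unchanged tiles had an unadjusted p under 0.05. When the noise was shared within the pairs I with III and II with IV, at the correlation of 0.70 estimated from the data, 65% and 97% of the shifts were recovered, 232 unchanged tiles were called, and 19.0% had an unadjusted p under 0.05. With each pair averaged first, the same noise gave 17% and 95% recovered, 40 unchanged tiles called and 5.8%. The p-values of the 4-replicate fit are therefore too small if these pairs are not independent, and the counts of all tiles, above and below the median, are also given with averaged pairs. On the real data, limma's spread in that averaged fit was in effect pooled over all tiles and does not measure each tile's own. Few simulated tiles were shifted, so the adjusted threshold was far stricter in the simulation than in the real 4-replicate fit. In the real fit 17994 tiles passed it, against 18144 with an unadjusted p under 0.05. The simulated recoveries and counts of unchanged tiles called therefore do not carry over to the real fit. For unchanged tiles the simulated shares with an unadjusted p under 0.05 are the closer guide. Counts by plate, series and run rest on the 4-replicate fit alone. The neighbour correlations were tested on simulated plates: offsets of whole plates alone gave an r of -0.01 between neighbours once plate medians were removed, and a true r of 0.7 that ignored plates was recovered as 0.72 across plate boundaries. The edges of low runs of at least 9 plates were located as the best single change point over 2 plates on either side. Those of TC17 to TC25 were left out, because the plates next to that run in number are not listed. A step of 2 placed at a plate boundary, on the values of other plates minus their medians, was located more than 5 tiles away in 13.7% of 322 sets.

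The alternatives were values without centring, centring on the mode, equal median absolute deviations, quantile normalization, a minimum change, each dye orientation alone, each slide-sharing pair alone, a mixture model, rank correlations, and leaving out each replicate in turn. Averaging or blocking the pairs I with III and II with IV, another reading order of the wells, and leaving out the low plates were added later.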

Results

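Histone H3 dimethylated at lysine 4 (H3K4me2), a modification known from textbook work to mark the genes of euchromatin, was profiled by chromatin immunoprecipitation on a tiling array of Arabidopsis thaliana chromosome 4. The material was seedlings of the accession C24, grown for 10 days in liquid culture. Immunoprecipitated DNA (IP) was hybridised against the input DNA of the same chromatin in 4 replicates, called I to IV, each from 50 µg and each on a pair of arrays with the dyes exchanged. The labels do not say whether the 4 replicates came from separate cultures, so p-values measure only the spread between these samples. The study concerned epigenomic change in hybrids between accessions. In this part of it C24 was measured alone, so the comparison it allows is IP against input along the chromosome, and no comparison between accessions or with a hybrid was made.

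The 8 columns held 4 sets of measurements. In every replicate all 21296 features with a value had identical values in both dye orientations, and the rest of the 21800 features were blank in both. Each dye swap was therefore counted as 1 sample and n was 4. Values were present for 21296 of the 21761 tiles in all 4 replicates, and the 39 control features had none. The values are log ratios of the 2 channels. Their log base and their direction (IP over input, or input over IP) are not given in the sources used here, so tiles are described below as above or below the median of their array, in deposited log ratio units, and not as enriched or depleted. No table used here ties a tile to a gene or to a coordinate, and tiles are named by their ID, which has the form of a plate and a well.

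The log ratio had a long tail on the low side (the histogram by replicate). Relative to the array median, the 5th percentile lay at -2.89 ± 0.10 (SD, n = 4) and the 95th at 1.81 ± 0.07. The 1st and 99th percentiles were -3.69 ± 0.05 and 2.38 ± 0.09. The spread over tiles was nearly equal in the replicates, with an SD of 1.44 ± 0.01. A mixture of 2 normal distributions described the mean log ratio better than 1, with a Bayesian information criterion lower by 2027. Its low component was centred at -1.60 with an SD of 1.09, and its high component at 0.61 with an SD of 0.84. A tile was more likely to belong to the low component in 7000 cases.

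**Figure D1:**
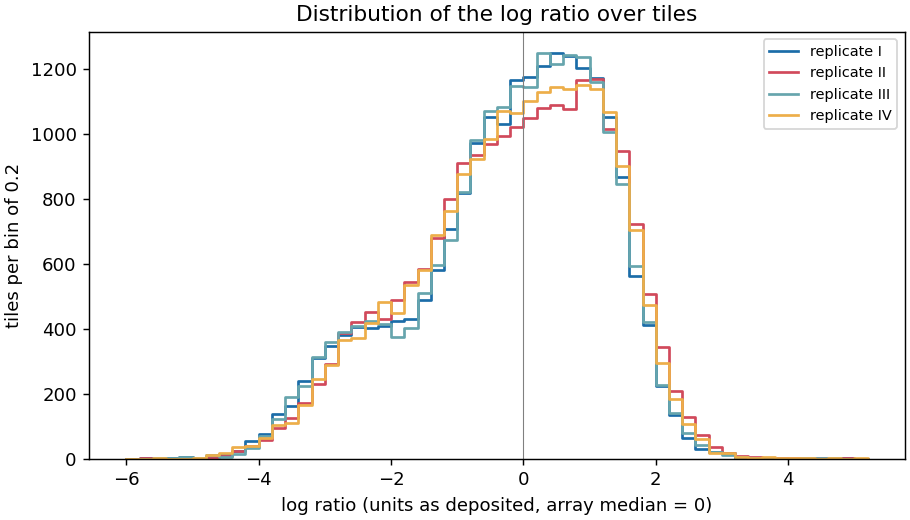
Number of tiles per bin of 0.2 (y axis) by log ratio relative to the array median (x axis, deposited log ratio units), 1 line per replicate. All 4 lines have a shoulder on the low side, and the 5th percentile lies at -2.89 ± 0.10 (SD, n = 4) against 1.81 ± 0.07 for the 95th.

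Most tiles differed from the array median by more than the spread between replicates. With limma's moderated test on the 4 replicates, 17994 of 21296 tiles passed a Benjamini-Hochberg adjusted p of 0.05, of which 8985 were above the median and 9009 below it. With the replicates I and III averaged, and II and IV, 8080 tiles were above and 8128 below, in a fit whose spread was in effect pooled over tiles. The median standard error of a tile's mean was 0.11. Of the tiles past the threshold, 17783 had the same sign in all 4 replicates. The near-equal split follows from centring on the median: with the values as deposited 4370 tiles were above 0 and 11699 below. With each array centred on its mode the counts were 4789 and 12143. The mode lay above the median by 0.57 in I, 0.96 in II, 0.52 in III and 0.49 in IV. Centring on the mode therefore also shifted II against the other replicates. When a difference of more than 0.58 was required, which is a 1.5-fold change if the base is 2, 5609 tiles were above and 6242 below.

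The tiles farthest from the median were named by a rule fixed before the data were examined, among those past the threshold with 1 sign in all replicates. The highest were TB65A08, at 4.85 ± 0.19 (SD, n = 4; limma adjusted p = 2.4e-07), and TA94E02, at 4.80 ± 0.16 (limma adjusted p = 2.4e-07). The lowest were TA37C01, at -5.42 ± 0.14 (limma adjusted p = 2.4e-07), and TA23A01, at -5.17 ± 0.50 (limma adjusted p = 3.1e-07). TB65A08 lay between TB65A07 at 1.41 and TB65A09 at 0.18, and TA94E02 between TA94E01 at 1.51 and TA94E03 at 1.93. TA37C01 lay between TA37B12 at -2.17 and TA37C02 at -3.07, and was itself far below the median of its plate, -2.35. TA22H12, before TA23A01, was at -4.40, and the other neighbour of TA23A01 had no value. Over the 20 highest tiles the median was 3.37, and their neighbours' means had a median of 0.67. Over the 20 lowest the corresponding values were -4.55 and -3.83.

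The replicates ranked the tiles alike, but not equally so for every pair. Pearson's r across tiles, which are not independent replicates, was 0.986 between I and III and 0.987 between II and IV. In the other 4 pairs it was lower, from 0.945 (III with IV) to 0.950 (I with IV). The SD of the tile-by-tile difference was 0.24 for both I with III and II with IV, and from 0.45 to 0.48 for the others. The deposited medians were -0.79 in I and -0.89 in III, and -0.46 in II and -0.35 in IV. Each array's label carries a pair of slide numbers, of which the former differs on every array. By the latter, I shared a slide number per dye orientation with II, and III with IV. These pairs had r = 0.948 and r = 0.945. Within these slide-sharing pairs alone, 15939 tiles (I and II) and 15656 tiles (III and IV) passed limma's test. Averaging I with III and II with IV to 2 values left 16208 tiles past the threshold, of which 16153 were among the 17994 and had the same sign. In these fits of 2 values per tile the moderated spread was in effect pooled over all tiles. TB65A08, for example, had a limma adjusted p of 4.5e-103 with averaged pairs. Counts from such fits therefore do not rest on each tile's own spread.

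**Figure D2:**
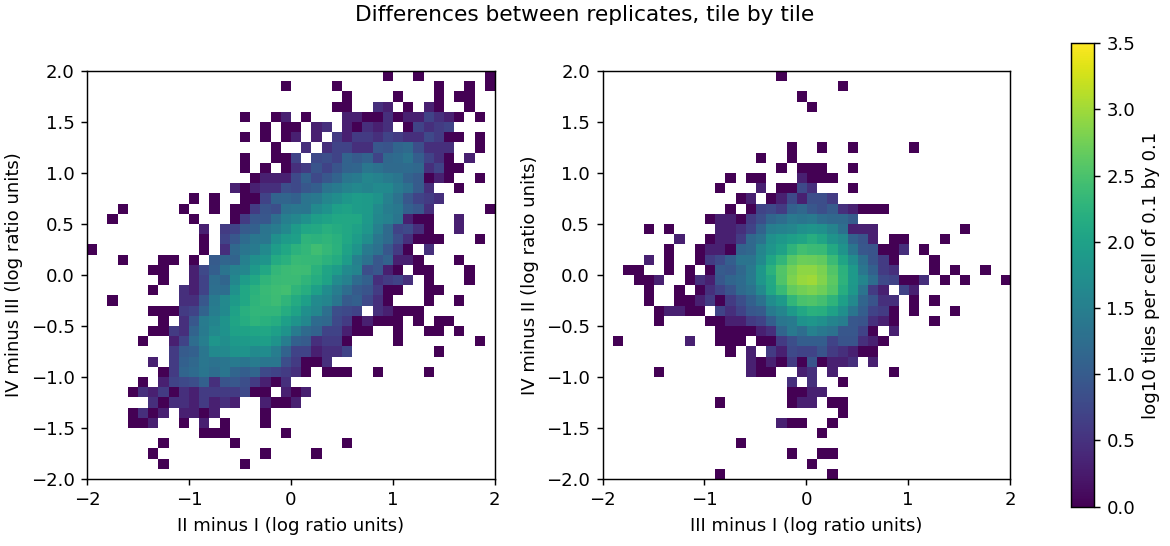
Tiles by their differences between replicates (deposited log ratio units, both axes limited to values from -2 to 2), with color for the log10 number of tiles per cell of 0.1 by 0.1. The difference II minus I rises with IV minus III (r = 0.729 over all tiles), and III minus I has no such relation to IV minus II (r = -0.06).

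Low log ratios were concentrated on certain plates, a pattern examined after the values were seen. Of 231 plates, 44 had a median more than 1 below the array median, and 42 of them did so in every replicate. These 44 plates held 18.0% of the measured tiles and 73.4% of the tiles more than 2 below the median (2093 of 2852), and 46.9% of the 7000 tiles of the mixture's low component, so that most of that component lay on other plates. On them 3443 of 3838 tiles (89.7%) were below the median by the limma test and 214 were above, against 5566 of 17458 (31.9%) below and 8771 above on the other plates. The median of all tiles on the 44 plates was -2.12 ± 0.13 (SD, n = 4), and on the other plates it was 0.30 ± 0.01. The difference of 2.42 ± 0.12 had the same sign in 4 of 4 replicates. The plates were chosen by this value, so the difference describes its size only.

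The low plates followed each other in number (the plot of plate medians). In the TA series, plates TA21 to TA30 had a median of -2.04 ± 0.12 (SD, n = 4), with 681 of 824 tiles below the array median. Plates TA37 to TA51 had a median of -2.24 ± 0.13, with 1266 of 1343 tiles below. Between these runs, plates TA31 to TA36 had a median of -0.08 ± 0.03, with 237 tiles below and 213 above. The middle plates were higher than TA21 to TA30 by 1.96 ± 0.11 and higher than TA37 to TA51 by 2.16 ± 0.13, each in 4 of 4 replicates. The plates were grouped by these medians, so the differences give their size and not a test. Shorter low runs followed at TA53 (-1.21 ± 0.04), TA57 to TA59 (-1.42 ± 0.05), and TA62 and TA63 (-1.75 ± 0.09). In the TC series, plates TC17 to TC25 had a median of -2.32 ± 0.12, with 746 of 783 tiles below, and TC27 to TC30 one of -1.95 ± 0.25. Taken in the order of the plates listed, the low plates formed 6 runs. In 100000 random orders of the plates the number of runs had a median of 36 and was never below 25 (permutation p = 1e-05, one-sided, the smallest these permutations can give).

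**Figure D3:**
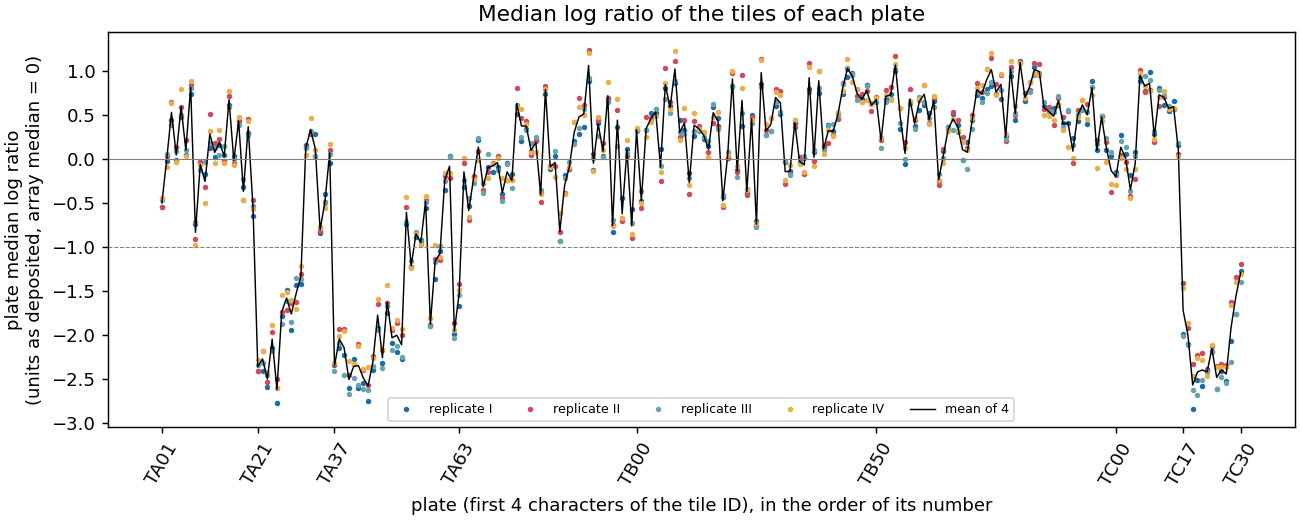
Median log ratio of the tiles of each plate (y axis, deposited units relative to the array median) in the order of the plate number (x axis), with a point per replicate and a line for the mean of the 4. The dashed line marks 1 below the array median, and plates TA21 to TA30 (-2.04), TA37 to TA51 (-2.24), TC17 to TC25 (-2.32) and TC27 to TC30 (-1.95) lie under it.

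The TB series, with 100 plates, had no plate more than 1 below the array median, and 5348 of its 9462 measured tiles were above the median by the limma test against 2451 below. Its median of 0.48 ± 0.02 (SD, n = 4) exceeded that of the TA series, -0.53 ± 0.02, by 1.01 ± 0.04 in 4 of 4 replicates (exact two-sided sign-flip permutation p = 0.13, the smallest possible). The sign flips count the 4 replicates as independent, which the resemblance of I to III and of II to IV puts in doubt. The plates with the highest medians, picked after their values were seen, were TB80 at 1.10 ± 0.01, TB54 at 1.07 ± 0.08 and TA90 at 1.07 ± 0.18. The TC series as a whole had a median of -0.75 ± 0.06, the 4 plates of the PD series one of -0.21 ± 0.05, and the single TD plate one of 0.76 ± 0.15. No TC plate had a median near that of the TC series. The medians of TC00 to TC13 ran from -0.35 to 0.95, and those of TC17 to TC30 from -2.57 to -1.29.

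Neighbouring tiles had similar log ratios (the plot of correlation by distance). With tiles of the TA, TB and TC series read along the rows of each plate, Pearson's r between adjacent tiles was 0.73 ± 0.01 (SD, n = 4 replicates). It was 0.61 ± 0.01 at a distance of 2 tiles, 0.48 ± 0.02 at 5, 0.43 ± 0.02 at 12 and 0.34 ± 0.03 at 96 tiles, the size of a full plate. After each plate's median was removed, the r between adjacent tiles of a plate was 0.56 (95% bootstrap interval over plates, 0.54 to 0.58), and it fell to 0.13 at a distance of 5 tiles and 0.03 at 12. The last tile of a plate and the first of the next-numbered plate had an r of 0.74 over 214 boundaries (95% bootstrap interval 0.65 to 0.81). With these boundaries shuffled 1000 times the highest r was 0.23. Over the 170 boundaries between plates that were not low, the r was 0.59 (95% bootstrap interval 0.45 to 0.72). Read down the columns of the plates instead, adjacent tiles had an r of 0.43, and without the 44 low plates the r along rows was 0.60.

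**Figure D4:**
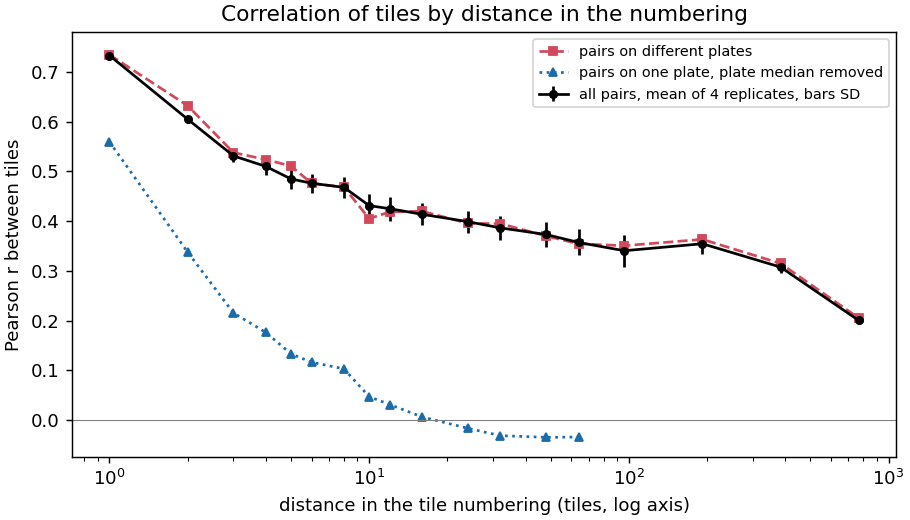
Pearson's r between the log ratios of tiles (y axis) against their distance in the tile numbering (x axis, tiles, log axis), for all pairs (mean of 4 replicates, bars SD), for pairs on different plates, and for pairs on the same plate after removing the plate median. For adjacent tiles the values are 0.73, 0.73 and 0.56, and the last series is at 0.03 by a distance of 12 tiles.

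Outside the low plates, tiles above and below the median came in short runs. The low plates were taken out before runs were counted, so the tiles on either side of a removed block counted as consecutive. Consecutive tiles above the median by the limma test formed 2292 runs with a mean length of 3.75 tiles and a longest run of 34. In 100 shuffles of the tile order the mean length was at most 2.01. Consecutive tiles below the median formed 2025 runs with a mean length of 2.67 tiles and a longest run of 31. In the shuffles their mean length was at most 1.48. Tiles bordering the long low runs of the TA series were themselves low. The longest run below the median may therefore join such tiles across removed plates. Runs of 5 tiles or more held 59.1% of the tiles above the median (at most 20.1% in the shuffles) and 42.6% of those below (at most 4.9%).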

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

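The correlations between replicates were planned, and the other tests in this part were chosen after the values had been seen. One value was set apart from its group: among the 31 sets of 4 replicate values examined, plate TA53 had 1 replicate away from the rest, with a gap of 0.846 of the whole range. Its medians were -1.22 in I, -1.23 in II, -1.15 in III and -1.24 in IV. Chance sets apart about 1 in 20 such groups.

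The resemblance of replicate I to III and of II to IV did not follow the slide number shared in the labels. Its r was 0.986 and 0.987, against at most 0.950 in the other pairs. The pairs that share a slide number, I with II and III with IV, had an r of at most 0.948. Each array's label also carries another number that no other array has, so these pairs share only part of their slide numbers. Independent measurement noise in each replicate is argued against by the resemblance itself, which can also be written as an r of 0.729 across tiles between the differences II minus I and IV minus III; this r follows from the spreads of the pairwise differences and is no further evidence. The difference II minus I was also similar in neighbouring tiles (r = 0.404, and 0.37 for IV minus III, against 0.08 for III minus I and 0.15 for IV minus II). A common chromatin or immunoprecipitation preparation of I and III, and another of II and IV, is a candidate explanation, but a labelling or hybridisation difference shared within the pairs could give the same values, and the labels do not decide between them.

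In 3 of 4 relations examined, plates 2 apart were more alike in these differences than adjacent plates, beyond shuffled plate orders after adjustment. The relations of II minus I and of IV minus III in a series are not independent, because these differences are correlated across tiles (r = 0.729). In the TB series the plate medians of II minus I had an r of -0.312 between adjacent plates and of 0.369 between plates 2 apart, and those of IV minus III had -0.08 and 0.55 (one-sided permutation tests of the plate order, p = 3e-05 and 6e-05, Benjamini-Hochberg adjusted over 6 such relations to 9e-05 and 0.00012). In the TA series the r was -0.13 for adjacent plates and 0.67 for plates 2 apart for IV minus III, with permutation p = 1e-05, the smallest these permutations can give (adjusted 6e-05). For II minus I in the TA series it was 0.05 and 0.32, with permutation p = 0.035 (adjusted 0.052), which does not pass 0.05 after adjustment. Differences along the chromosome alone would make adjacent plates at least as alike as plates 2 apart, which the 3 relations that pass argue against. Alternating plate sets in handling or printing may account for this part, but stay open, since II minus I in the TA series did not pass. The SD of these plate medians, 0.12 to 0.19, was far below that of the plate medians of the log ratio itself in the TA series (1.02), for which the permutation test gave an adjusted p of 0.61. In the TB series, where that SD was 0.39, the alternation of the log ratio had an adjusted p of 0.12.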

How the results depend on the processing

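The settings with replicate pairs averaged or blocked, wells read down columns, low plates left out, and all those for the plates and for replicates left out of the mixture were chosen after seeing the data. Counts of tiles moved by over 1.5 times only with centring or with a minimum change. Without centring 4370 tiles were above 0, and with centring on the mode 4789, against 8985 with the median, and the share of called tiles that were above moved from 49.9% to 27.2% and 28.3%. The median of all tiles lay at -0.61 and -0.63 under these settings, so the side on which a tile near the median falls depends on the choice of zero. A minimum change left 11851 tiles, of which 5609 were above. Scaling, quantile normalization, the slide-sharing pairs alone, and the pairs I with III and II with IV averaged (16208) or as a random block (16607) stayed within 1.5 times the main count of 17994, as did leaving out each replicate (17372 to 17568). The fits of averaged pairs, of slide-sharing pairs alone and of values centred on the mode used a spread in effect pooled over all tiles. The low component of the mixture held 6646 to 7296 tiles with a replicate left out. The 4 named tiles kept their direction and their side of the threshold under every setting run. With centring on the mode, which also shifted II against the other replicates, 65 plates, in place of 44, lay more than 1 below 0. The correlation of neighbouring tiles fell to 0.43 when wells were read down the columns and to 0.60 without the low plates, and that across plate boundaries fell from 0.737 to 0.595 without them. Using only 1 dye orientation, or only tiles measured on all arrays, changed nothing, since these settings hold the same values, and they say nothing about stability. The fit of 8 arrays with a dye term, and all alternatives for genes, gene lists, annotation classes, regions, positions within genes and the dye effect, were not run, for lack of separate arrays or of tile positions. There is a single group, so no groups could be compared as pairs. The absence of scanner intensities means that tiles near background cannot be told from the rest.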

Other observations

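The tests of plate-wise handling and of the numbering in the paragraph on low plates were set out before their results were known, after the low plates themselves had been seen; the other tests of this part were chosen after the values had been seen. The longest runs of low plates are TA21 to TA30, TA37 to TA51 and TC17 to TC25, with shorter ones at TA53, TA57 to TA59, TA62 to TA63 and TC27 to TC30. Plate-wise handling is argued against as the only cause of the long runs in the TA series. Of the 4 edges examined, all in that series, 3 had the change in level more than 5 tiles from the plate boundary. It lay on the same side of the boundary in every replicate. No edge of TC17 to TC25 was examined. All replicates measured the same tiles, so their agreement on a location is not independent evidence. The tiles next to each run were set off at the change point found in these same values. The levels that follow therefore give its size and not a test. In plate TA20 the 16 tiles next to the low run had a median of -3.12 ± 0.27 (SD, n = 4) against -0.16 ± 0.11 for the rest of the plate. In TA31 the values were -2.07 ± 0.19 for 16 tiles and 0.27 ± 0.05, and in TA36 -2.22 ± 0.05 for 19 tiles and 0.41 ± 0.17. At the edge with TA52, which met the same limit of 5 tiles in every replicate, the replicates placed the change on different sides of the boundary, so that edge has no common location and is not counted here, and the levels differed less there (-1.65 ± 0.21 for 17 tiles and -0.45 ± 0.08 for the rest). A numbering that follows the chromosome was also tested: after plate medians were removed, the last and first tiles at plate boundaries had an r of 0.548 (95% bootstrap interval 0.42 to 0.66), where shuffled boundaries gave at most 0.24.

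Chromosome 4 of the reference accession carries a heterochromatic knob on its short arm as well as its pericentromere. Heterochromatin is known to be poor in H3K4me2, so it is a candidate explanation for the low runs of the TA series. If so, the deposited ratio would run as IP over input. This was not tested, because it needs the positions of the tiles, and the r of 0.548 speaks for a continuous numbering without saying where on the chromosome it lies. Whether C24 carries this knob was not examined either. The low runs of the TC series come last in the numbering, after the TB series, which has no low plate. Whether heterochromatin could account for them too was not examined. Cross-hybridisation of repeated sequence stays open too.

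Of the 20 highest tiles, 5 had a tile without a value within 2 wells, and of the 20 lowest 9 did, against 6.8% of all other tiles. Since blanks and extreme tiles both cluster, the counts were set against all 21349 circular shifts of the blank positions along the numbering (one-sided permutation p = 0.020 and 0.0096, adjusted over both tests to 0.020 and 0.019). Tiles without a value were themselves clustered: 49 adjacent pairs both lacked one, against at most 20 in 1000 shuffles, and plates TB58, TA94 and TC25 lacked 19 values each. On the low plates 2.8% of tiles lacked a value, and on the others 2.0%. The low plates differed widely in this: TA25 had values for 77 of 95 tiles, and TA43 for 96 of 96.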
